A study of Rhodopseudomonas palustris with 6 samples.

How the data were processed

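Total RNA was measured in 6 samples of the photosynthetic bacterium Rhodopseudomonas palustris by not-so-random RNA-seq, in which a selected mix of short primers is used for first-strand and second-strand synthesis. Per the labels' protocols, cells grew photoheterotrophically with 10 mM succinate at 30 °C, were treated at an optical density of 0.1 and were collected at 0.5, and the RNA was treated with DNase. The signal, p-coumaroyl-homoserine lactone (pC-HSL), was given at 10 µM. The groups were the wild-type strain CGA009 without the signal (2 libraries) and with it (1 library), and the rpaR mutant CGA850 without the signal (2 libraries) and with it (1 library). The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

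The deposited files list 1 aligned read per line, with its start, end, strand and a mapping quality score. Per the submitters' processing notes, BWA was used, with no version given; the chromosome record named in the files is BX571963.1, and coordinates are positions on it, counted from 1. Mismatch limits and the treatment of unaligned reads are not given in the sources used here. Alignments spanned 29 to 33 bases. The mapping quality score was 0, the value for reads that fit more than 1 place equally well, in 63.3% to 70.2% of reads.

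Before the data were examined, reads were planned to be counted per annotated gene. The only gene table in hand, for the strain RCB100 (assembly ASM1658444v1), has no positions on the record used here, and coordinates were not converted. Reads were therefore counted in 500-base windows on each strand, by read midpoint, a choice made after seeing the data. As a stand-in for the planned removal of ribosomal and transfer RNA genes, 142 windows in which over 50% of reads had a mapping quality of 0 were left out of tests and library sizes; they held 65.6% to 71.8% of each library's reads. Called windows on the same strand and in the same direction were merged into regions where at most 500 bases lay between them. The planned tests of 20 gene lists, the values of the rpaI and rpaR genes by name, the division of the rpaR gene into 5 parts and a second count tool were not run.

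The strand of the RNA was taken as opposite to that of the alignment. This was checked with 4 conserved 16S ribosomal RNA sequences, taken from general knowledge: each matched the sequence rebuilt from the 6 bases in the read names, with 0 to 2 mismatches on the minus strand and at least 5 on the plus strand, where reads align to the plus strand. Among reads with a mapping quality of 0, 0.168% to 0.224% lay on the other strand; among 5761 windows with at least 100 reads, the median share on the more-read strand was 98.0% (lower quartile 91.1%), where the rest can hold strand errors and RNA of both strands.

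Windows entered the tests with at least 10 reads in 1 library and at least 20 over the 6 libraries, which left 9915. Trimmed mean of M values factors, written out in R 4.3.3, lay between 0.879 and 1.24. Group means were fitted to all 6 libraries with limma 3.58.1 (voom weights, robust empirical Bayes), and 2-sided p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The spread comes from the 2 replicated groups alone (2 residual degrees of freedom per window, moderated across windows), and each single library is assumed to vary like them. Values per library are CPM, reads scaled to the normalised library size. Fold changes come from the fit, with 95% confidence intervals. Where a group had no reads, the fold is a lower bound against 3 counts over the group. Reads from PCR without molecular identifiers are not independent molecules, so intervals from counts and these bounds cover counting error only. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

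Named windows followed the rule fixed for genes: in each contrast and direction, up to 12 with the largest fold change among those past the threshold, with at least 50 reads in a library of the higher group and no overlap between groups, here 1 window per region; directions with under 5 were filled to 5 with windows that did not pass. Windows around the segment without mutant reads were added after their values were seen.

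The script was tested on simulated counts for the wild-type comparison over 9915 windows (dispersion 0.029, 5 draws of 200 changed windows). Windows with a mean of at least 50 reads were recovered in 23.3% of cases for 2-fold changes, 96.6% for 4-fold and 99.0% for 8-fold; below 50 reads the shares were 4.31%, 44.7% and 67.7%. False calls made up 4.57% of calls. Every simulated library had the same dispersion, so this share does not cover a single library that deviates from the rest. The dispersion was estimated only from windows with a mean of at least 50 reads in a replicate pair. The shares for shallower windows, and the share of false calls, may therefore be too favourable. Alternatives covered normalization, the low-count filter, the test, strand, mapping quality, identical reads, the replicate number as a block, the libraries in the fit and leaving out each replicated library. Other window sizes, a shifted grid, leaving out each window's most-read position and crossed replicate numbers were chosen after seeing the data.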

Results

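The series asked which transcripts of R. palustris respond to pC-HSL, an acyl-homoserine lactone with an aromatic side chain, and which of these responses need RpaR, the LuxR-type regulator that binds it. Libraries held 8080689 to 10462133 aligned reads, of which 2419531 to 3429264 lay outside windows dominated by reads that fit several places. Segments at 4992001 to 4998000 and 5246001 to 5251500, both read as minus-strand RNA, took 35.0% and 33.1% of all reads. Of the reads left for the tests, 31.5% to 39.4% fell in only 4 windows. Log2 CPM of replicate libraries had a Pearson correlation of 0.958 across 8202 windows in the untreated wild type and 0.964 across 7121 windows in the untreated mutant. Positions below are on the chromosome record BX571963.1, for which no gene annotation was used, so regions are given by position and RNA strand, without gene names.

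The targeted gene could not be read by name. In the 3 rpaR mutant libraries, a segment of 752 bases from 349347 to 350098 held 0 reads on either strand. The segment was found by scanning the genome for stretches without mutant reads, so the 0 follows from the choice. In wild type the same segment held 17 and 43 reads of minus-strand RNA in the untreated libraries and 25 in the treated library. Plus-strand RNA over it counted 1 and 20 reads without the signal and 223 with it. Minus-strand RNA in window 349501 to 350000 was at 6.81 ± 1.04 CPM (reads scaled to the normalised library size, SD, n = 2) in untreated wild type, at least 11.6-fold higher than in the untreated mutant by counts, although the fitted difference did not pass the test (limma adjusted p = 0.453). The window lies inside the chosen segment, so this bound is not a measure of a strain difference independent of the choice. The adjoining 1400 bases on the right held 62 to 99 minus-strand reads in each mutant library and 87 to 133 in each wild-type library.

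**Figure D1:**
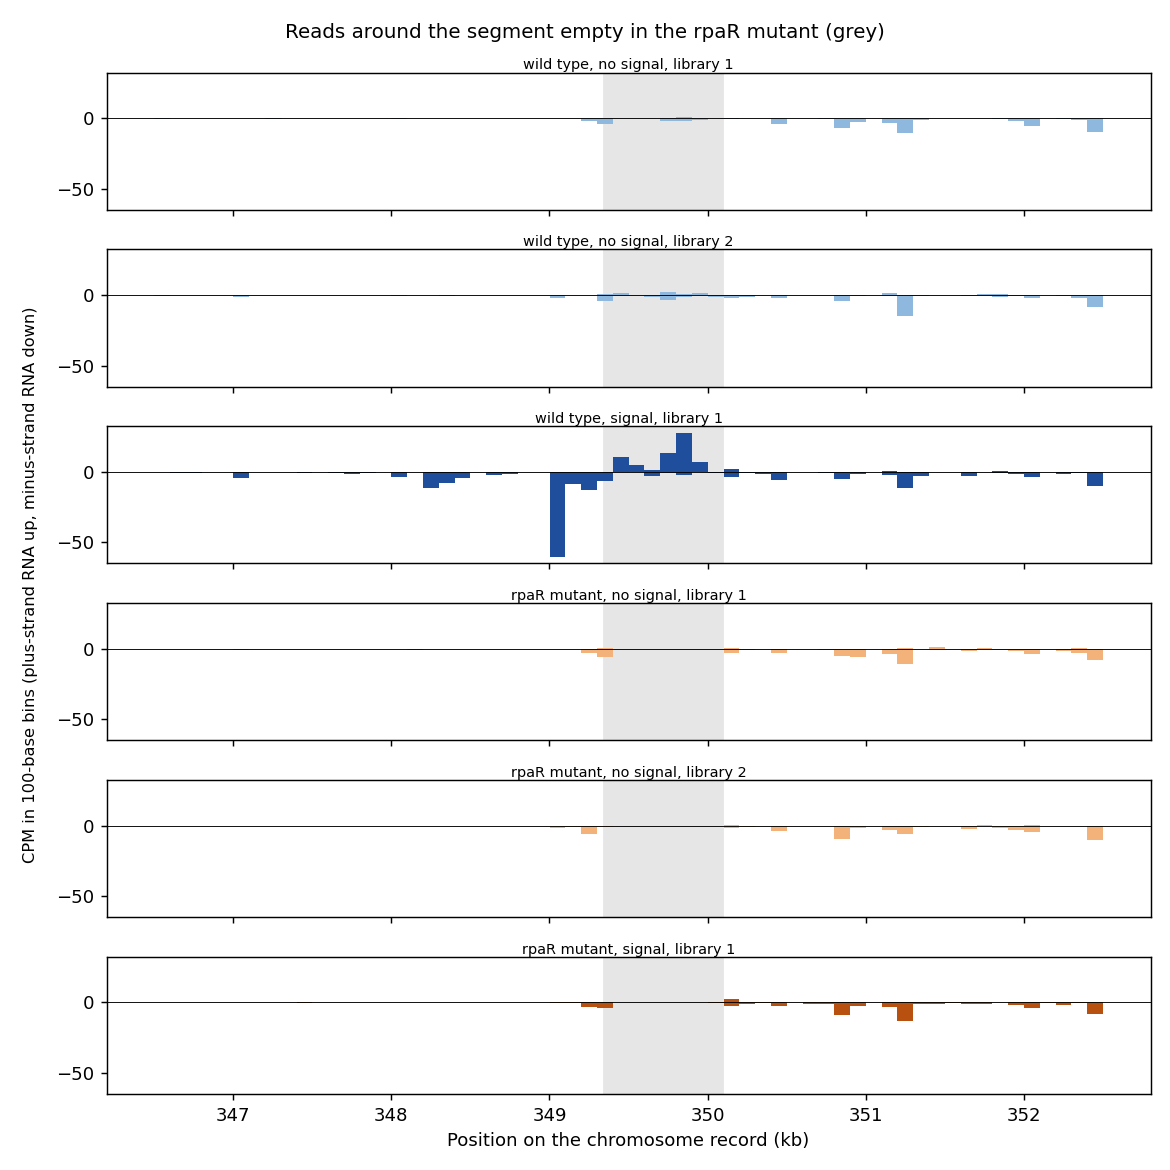
CPM in 100-base bins for each library, with plus-strand RNA above and minus-strand RNA below the axis; the grey band is the segment from 349347 to 350098. The band was chosen because the mutant libraries have 0 reads in it. The treated wild-type library has 223 plus-strand reads there, and the bin across the left edge of the band also holds reads from outside it.

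In the wild-type library with pC-HSL, 57 regions (94 windows) rose and 15 regions (23 windows) fell against the untreated libraries, among 9915 windows. Among the named windows, large rises lay around the segment described above. Plus-strand RNA at 349501 to 350000 went from 1.96 ± 2.23 CPM (SD, n = 2) to 53.5, a 28.5-fold rise (95% interval 10.1 to 80.5, limma adjusted p = 1.51e-06); the rise was 14.7-fold without untreated wild-type replicate 1 and 94.2-fold without replicate 2, and 8.72-fold (adjusted p = 0.0413) with identical reads counted once. Immediately to its left, minus-strand RNA rose at 348001 to 349500, by 16.8-fold in window 348001 to 348500 (5.97 to 47.5, limma adjusted p = 9.21e-05), or 12.4-fold and 29.2-fold without untreated wild-type replicate 1 and 2. That window did not pass with limma trend (adjusted p = 0.0522) or with identical reads counted once (7.74-fold, 0.0683). In the same region, the minus-strand window at 349001 to 349500 held more reads. It had 16 and 36 without the signal and 309 with it (log2 change 3.56 ± 0.37, SE). Elsewhere, window 4063501 to 4064000 on the plus strand rose 22.0-fold (9.57 to 50.5), or 15.8-fold and 40.6-fold without untreated wild-type replicate 1 and 2, and did not pass with identical reads counted once (7.81-fold, adjusted p = 0.0595).

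Several abundant transcripts also rose. Minus-strand RNA at 1204001 to 1204500 went from 55.7 ± 1.79 to 704.1 CPM, 12.6-fold (8.73 to 18.3), with the smallest adjusted p of the comparison (4.39e-22). Plus-strand RNA at 3189001 to 3190000 rose 7.10-fold in its leading window (4.98 to 10.1), from 116.8 ± 10.5 to 831.3 CPM. A plus-strand region at 4376001 to 4378000 rose 5.90-fold in its leading window (4.16 to 8.39), from 795 ± 216.4 to 4597.7 CPM. With identical reads counted once, the leading windows of these 3 rose 2.40-fold, 2.36-fold and 2.00-fold, each still past the threshold. Some regions extended over kilobases, such as 3815501 to 3819000 on the minus strand (6 windows), 2123501 to 2126500 on the minus strand (6 windows) and 2134501 to 2137000 on the plus strand (5 windows).

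The falls were led by plus-strand RNA at 2075001 to 2075500, which dropped 13.7-fold (4.97 to 37.6) from 33.1 ± 3.85 to 2.3 CPM. Minus-strand RNA at 2104001 to 2105000 fell 11.1-fold in its leading window (6.63 to 18.7, limma adjusted p = 1.69e-12), from 139.3 ± 11.1 to 12.4 CPM. A minus-strand region at 3218001 to 3219500 fell 6.69-fold in its leading window (log2 -2.74 ± 0.37, SE), and a plus-strand region at 2388001 to 2390500 fell in 5 windows. With identical reads counted once, the leading windows at 2075001, 2104001 and 3218001 fell 3.11-fold, 2.46-fold and 2.42-fold and did not pass (limma adjusted p = 0.506, 0.0787 and 0.754).

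**Figure D2:**
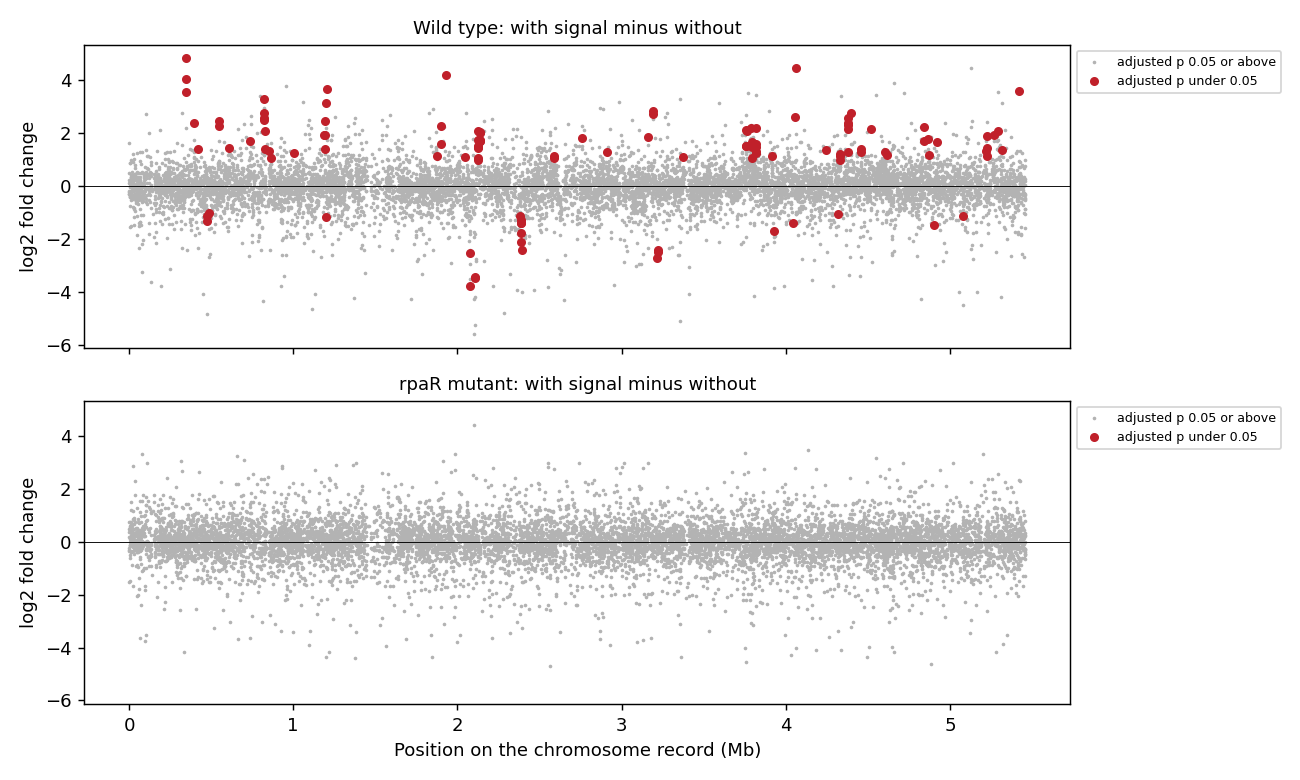
Log2 fold change of each of 9915 windows with the signal against without it, along the chromosome record, in wild type (top) and in the rpaR mutant (bottom); red points passed an adjusted p of 0.05. Wild type has 94 red points above 0 and 23 below, and the mutant has 0.

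These calls rest on 1 treated library. Without the low-count filter 34 regions fell, and 27 fell with the crossed replicate block, chosen after seeing the data. Counting identical reads once left 22 regions that rose and 3 that fell, limma trend gave 33 that rose, and leaving out untreated wild-type replicate 1 gave 122; without either untreated mutant library 8 regions fell.

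**Figure D3:**
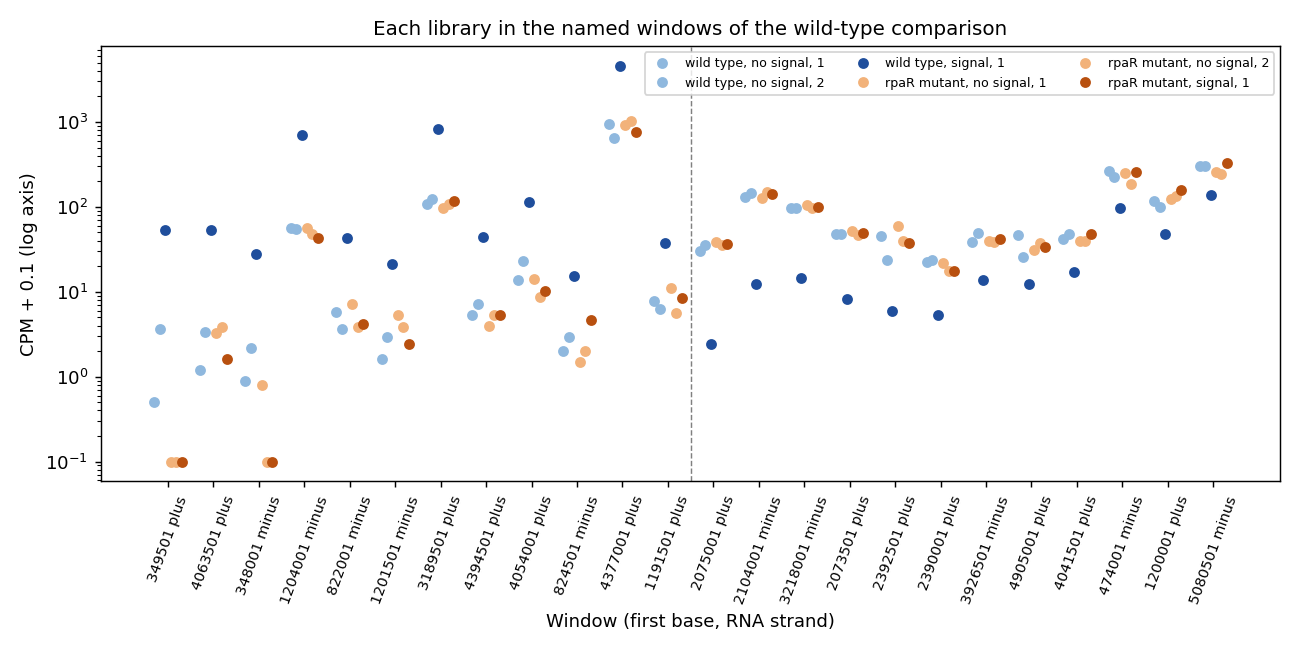
CPM plus 0.1, on a log axis, in each of the 6 libraries for the 12 named windows that rose (left of the dashed line) and the 12 that fell in wild type with the signal. By the rule for naming, in each window the treated wild-type library lies apart from both untreated wild-type libraries.

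With the signal in both strains, wild type exceeded the rpaR mutant in 35 regions (52 windows) and was below it in 14 regions (21 windows). Plus-strand RNA at 349501 to 350000 was at least 47.3-fold higher in wild type, where the mutant had 0 reads, and minus-strand RNA at 348001 to 348500 at least 24.4-fold higher. The first of these windows lies inside the segment chosen for its lack of mutant reads. If that sequence is missing from the mutant, its bound does not measure a response that needs RpaR. The second window lies partly in another stretch without mutant reads, from 348200 to 349021. Minus-strand RNA at 349001 to 349500, a window that crosses the left edge of the chosen segment, had 309 reads in treated wild type and 22 in the treated mutant. Its log2 difference was 3.39 ± 0.49 (SE). The window at 1204001 to 1204500 was 16.3-fold higher (10.3 to 25.9) and that at 3189501 to 3190000 was 7.08-fold higher (4.64 to 10.8). Minus-strand RNA at 5223001 to 5223500 was 9.88-fold higher (5.53 to 17.6), with 143.3 CPM in treated wild type and 14.3 in the treated mutant. Untreated libraries were at 52.2 ± 2.47 CPM in wild type and 40.2 ± 11.6 in the mutant (SD, n = 2). Part of this gap is therefore the lower value of the treated mutant library. In the other direction, the window at 2104001 to 2104500 was 11.2-fold lower in wild type (6.38 to 19.7) and that at 2075001 to 2075500 was 15.0-fold lower (5.27 to 42.9). This comparison sets 1 library against 1, and its counts ranged from 20 to 57 regions higher and from 8 to 33 lower when single replicated libraries were left out, with 57 and 33 without untreated wild-type replicate 1, 56 and 28 without wild-type replicate 2, and 20 and 8 without either untreated mutant library. The window at 348001 did not pass without untreated mutant replicate 1 (adjusted p = 0.154) or 2 (0.140), with total reads (0.0828), with ordinary empirical Bayes (0.0603) or with the replicate block (0.0517), and without the most-read position neither it (0.228) nor that at 349501 (0.105) passed. Identical reads counted once left 4 regions higher and 1 lower. Of the windows named by the rule for this contrast and given here, only those at 1204001 (2.74-fold) and 3189501 (2.56-fold) still passed.

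Calls shared with the wild-type response numbered 46 windows higher and 20 lower. Independent lists would share 0.493 and 0.0487 windows. In 100 simulations without any effect, in which both comparisons used the same treated wild-type library, the mean was 0 and 0.01; these simulations called at most 0.1 windows per direction on average, so they set no chance level for lists of this length. The covariance of the fold changes was 0.462, against 0.164 in the simulations. Their Pearson correlation across windows, which are not independent replicates, was 0.607 against 0.550. The simulated dispersion came only from windows with a mean of at least 50 reads in a replicate pair, so noise in shallower windows may be understated. The gap to the simulations therefore does not show a shared response. With 1 treated wild-type library it could not be split, so part of the overlap may come from the shared library. Leaving out untreated wild-type replicate 1 gave 77 shared windows higher, and leaving out untreated mutant replicate 1 or 2 gave 26 or 30 higher and 10 or 11 lower.

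In the rpaR mutant, pC-HSL gave 0 windows past the threshold with limma voom and 0 with limma trend; 408 windows had an unadjusted p under 0.05, where 495.75 would be expected by chance. The 94 windows that rose in wild type had a median log2 change of -0.16 in the mutant, against 1.70 in wild type, and 33 of them lay above 0. The 23 windows that fell had a median of -0.01 in the mutant, against -1.47 in wild type. Both lists were chosen by the wild-type test, which fixes the sign of the wild-type medians and can inflate their size. Windows chosen for noise in the treated wild-type library would also centre near 0 in the mutant. These medians therefore do not show a strain difference by themselves. Values named by the rule, which did not pass the test, included the minus-strand window at 1406501 to 1407000 (log2 1.87, adjusted p = 0.895) and the plus-strand window at 3915001 to 3915500 (log2 -1.46, adjusted p = 0.996). Without the low-count filter, 2 regions were called higher and 3 lower, and 1 and 1 were called with the mutant libraries alone or without either untreated wild-type library.

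The difference between the strains' responses was tested directly. Response to the signal was higher in wild type in 25 regions (38 windows) and lower in 8 regions (10 windows). Among the named windows, differences on the log2 scale were 5.54 ± 1.32 (SE) at 4063501 to 4064000, 3.93 ± 0.42 at 1204001 to 1204500 and, for falls, -3.76 ± 0.81 at 2075001 to 2075500 and -3.51 ± 0.47 at 2104001 to 2104500. Scaling by total reads changed the split to 13 regions higher and 12 lower (52% higher, against 75.8%), and moved the median of all windows by -0.29. Leaving out untreated wild-type replicate 1 gave 86 regions higher and 21 lower, leaving out wild-type replicate 2 gave 16 lower, and leaving out untreated mutant replicate 1 or 2 gave 13 or 10 higher and 5 or 3 lower. The difference at 4063501 did not pass without untreated mutant replicate 2 (adjusted p = 0.0847), with total reads (0.0565), with at least 50 reads required (0.127) or without the most-read position (0.0562), and it was 6.41 without untreated wild-type replicate 2. That at 2075001 did not pass with at least 50 reads required (0.0783) or without the most-read position (0.102). Identical reads counted once left 2 and 0, and none of the windows given here passed.

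Without the signal, the rpaR mutant and wild type, with 2 libraries each, differed in 0 windows by limma voom and 0 by limma trend; 506 windows had an unadjusted p under 0.05, where 495.75 would be expected by chance. Among values that did not pass, plus-strand RNA at 1190501 to 1191000 was at 38.6 ± 13.2 CPM in the mutant and 16.9 ± 8.89 in wild type, and plus-strand RNA at 3612001 to 3612500 was at 5.17 ± 0.66 and 16.4 ± 6.51 (SD, n = 2). The 0 depended on untreated wild-type replicate 1, without which 115 regions were higher and 15 lower in the mutant, against 0 and 0 without wild-type replicate 2. The fit without replicate 1 set the mutant against wild-type replicate 2 alone. Replicate 2 had the largest normalization factor of the 6 libraries, 1.24, and the smallest share of reads in the 4 most-read windows, 31.5%. These calls may therefore reflect replicate 2 and not a strain difference. Without the low-count filter, 17 regions were higher and 6 lower. Crossed replicate numbers as a block, chosen after seeing the data, gave 17 and 1. Minus-strand RNA at 349501 to 350000, with 0 reads in the mutant, was among the windows not called.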

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

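The windows here were named for a contrast and listed because their responses differed between wild type and the rpaR mutant by the interaction test (limma, adjusted p under 0.05). They include the 12 higher and 7 lower windows named for the interaction, which were ranked by the size of that difference. Passing the test therefore follows from the choice, and the sizes can be inflated by it. Differences below are log2 changes in wild type minus those in the mutant. The tests of single libraries, of chance absence, of missing sequence, of strand errors and of DNA were chosen only after the result was seen.

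Positive differences on the plus strand were 5.54 in the window starting at 4063501, 2.63 at 3189501, 2.75 at 4054001, 2.9 at 4377001, 2.63 at 3760501 and 2.56 at 1190501. On the minus strand they were 3.93 at 1204001, 3.65 at 822001, 3.68 at 349001, 2.89 at 5223001, 2.95 at 546001 and 2.84 at 4843001. Negative differences on the plus strand were -3.76 at 2075001 and -2.53 at 2073501. On the minus strand they were -3.51 at 2104001, -2.7 at 3218001, -3.03 at 3218501, -1.56 at 474001, -1.57 at 5080501, -2.54 at 3704501 and -2.96 at 1406501. In the last 2, neither the wild-type log2 changes, -1.50 and -1.09, nor those in the mutant, 1.04 and 1.87, passed the test on their own. At 5223001 the log2 change was 1.46 in wild type and -1.43 in the mutant, where it did not pass. With identical reads counted once, 10 of the 12 higher and 7 of the 7 lower windows named for the interaction could still be fitted, and 1 and 0 passed.

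All of the wild-type calls rest on the treated wild-type library. Set against the remaining 5 libraries, it gave 143 windows past the threshold, and the most that any other library gave was 3. Whether another single library differs as much stays open, because with untreated wild-type replicate 1 left out, the lone untreated wild-type replicate 2 gave 115 regions higher and 15 lower in the mutant, beside 122 and 22 for the signal in the same fit. With the most-read position of each window left out, 95.7% of the 117 called windows kept their sign and at least 50% of their log2 change, which argues against reads piled up at single priming positions, although 64 stayed past the threshold. A feature of that culture or library other than the signal cannot be told apart from the signal, because the design has 1 treated wild-type library, so a response that needs RpaR stays a hypothesis.

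The segment from 349347 to 350098, found by scanning the genome for stretches without mutant reads, held 329 wild-type reads. Of these, 18 and 63 came from the untreated libraries and 248 from the treated one. Stretches without wild-type reads held at most 28 mutant reads, or 32.9 at wild-type depth. Because most of the 329 came with the signal, that contrast does not measure chance absence. In the untreated libraries alone, the stretch without mutant reads that starts at 349347 had 83 wild-type reads. Stretches without wild-type reads had at most 30 mutant reads, or 33.4 at wild-type depth. In both scans depth was scaled by reads outside the left-out windows. Normalised library sizes would give a larger value than 33.4. The gap argues against chance absence at this depth, though how strongly depends on the scale. Sequence missing from the mutant, possibly the rpaR gene itself, is a candidate explanation. Each mutant library had at least 20 reads in the 1400 bases on either side, but 822 bases of the left side, from 348200 to 349021, also had 0 mutant reads, where the untreated wild-type libraries had 0 and 6. The RCB100 gene table lists rpaI next to rpaR, but no annotation of the record was in hand to show whether rpaR lies here. With these reads, a loss of transcription from intact sequence cannot be told apart from missing sequence.

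Plus-strand RNA in that segment had 223 reads in the treated wild-type library beside 25 minus-strand reads. That is 892 plus-strand reads for each 100 on the minus strand. Reads that fit several places lay on the other strand in at most 0.224%, and windows with at least 100 reads (5761) had a median of 98.0% on 1 strand (lower quartile 91.1%), so minus-strand reads assigned to the wrong strand could not be the main source. The plus-strand share was 89.9% (exact 95% interval 85.5 to 93.4). That interval treats reads as independent, although 96 of the plus-strand reads lay in the 100-base bin at 349801 to 349900. The share was above an even split, but a selected primer mix need not read both strands of DNA evenly. Carried-over DNA therefore cannot be excluded by this share. RNA made with the signal from the strand opposite to the minus-strand transcript is a hypothesis from 1 library, and untreated replicates already differed, with 1 and 20 reads. The interaction test in window 349501 to 350000 (limma adjusted p = 0.725) cannot decide it. The mutant had 0 reads there, so its log2 response had a standard error of 2.34.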

How the results depend on the processing

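Values here count regions unless windows are named, as higher and lower; the 1000-base, 250-base and shifted windows, the crossed numbers and the loss of each window's most-read position were chosen only after the result was seen. Mapping quality of at least 20 and median-of-ratios factors left 87 of 87 named values on their side of the threshold. Causes were not tested except where stated.

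For the signal in wild type, limma trend gave 33 higher, identical reads counted once 22 and 3, the most-read position left out 33 and 9, no filter 34 lower, 1000-base windows 8 lower and only the libraries of the contrast 9 lower. For wild type against mutant with the signal, no filter gave 78 and 33, identical reads counted once 4 and 1, the most-read position left out 14 and 8, and 1000-base windows 23 higher. For the signal in the mutant, no filter gave 2 and 3, and only the libraries of the contrast 1 and 1. For the mutant against wild type without the signal, no filter gave 17 and 6, and 250-base and shifted windows 1 lower each. For the interaction, total reads gave 13 higher, no filter 47 and 21, at least 50 reads 5 lower, identical reads counted once 2 and 0, and the most-read position left out 13 and 2. Windows shared by the first 2 contrasts numbered 5 and 1 with identical reads counted once, and 25 and 9 without the most-read position. Counting identical reads once caps each window at its number of positions, so it shrinks large counts by construction; the median size of the 117 wild-type log2 changes went from 1.70 to 0.79, 107 of the 109 windows still fitted kept their sign and 24 stayed past the threshold.

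Leaving out single replicated libraries, whose remaining partner is assumed to vary like the other groups, gave 40 to 122 higher and 8 to 22 lower for the signal in wild type, 20 to 57 and 8 to 33 for the strains with the signal, 0 to 1 and 0 to 1 for the signal in the mutant, 0 to 115 and 0 to 15 for the strains without it, 10 to 86 and 3 to 21 for the interaction, and 26 to 77 and 10 to 21 shared windows. The highest values came without untreated wild-type replicate 1. For the signal in the mutant they were equal without untreated wild-type replicate 2. The same held for regions that fell with the signal in wild type and for shared windows that were lower.

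Deviations of equally numbered libraries were negatively correlated (-0.24 across 3324 windows, 2 pairs), so equal numbers were not taken to pair samples. A negative value is the sign that crossed numbers would give. Whether unequally numbered libraries shared a feature stays open. The replicate block gave 38 and 13 for the signal in wild type, 27 and 11 for the strains with it, 0 and 0 for both comparisons without calls, and 24 and 6 for the interaction. The crossed replicate block gave 27 lower for the signal in wild type, 54 and 32 for the strains with it, 17 and 1 for the strains without it, and 41 and 17 for the interaction.

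Named values changed sign in 3 cases: the plus-strand window at 4041501 (log2 0.0532 with identical reads counted once and 0.307 without its most-read position) and that at 3915001 (0.253 with both strands counted together). Total reads moved the median log2 change of all windows to -0.12 for the signal in wild type, 0.16 in the mutant and -0.30 for the strains without it. The gene lists and the 5 parts of the rpaR gene were not run, because no annotation of the record used was in hand. DESeq2 was planned only for deposited counts per feature and was left out. Small changes were often missed in simulations of the wild-type comparison over 9915 windows. Recovery of 2-fold changes was 23.3% in windows with a mean of at least 50 reads. It was 4.31% below that, where the simulated dispersion was not estimated and the share may be too favourable.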

Other observations

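A few positions were called on both RNA strands with the signal in wild type. At 4376501 to 4377000 the minus strand rose by 1.29 on the log2 scale, inside the plus-strand region at 4376001 to 4378000. At 5223001 to 5223500 the plus strand rose by 1.16, opposite the minus-strand region at 5222501 to 5223500, which rose by 1.90 in its leading window. Neighbouring regions on opposite strands also rose at 1190001 to 1190500 on the minus strand (1.93) and 1190501 to 1192000 on the plus strand (2.46 in its leading window). These positions were picked after their values were seen, and strand errors were not weighed for them.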
